A study of Mus musculus with 4 samples.

How the data were processed

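Lung tissue was collected from mice at 2 months of age, total RNA was extracted, and libraries were made with a TruSeq kit and sequenced on an Illumina HiSeq, per the labels' protocols. The table deposited by the authors holds raw read counts per gene for 4 libraries and 21931 genes, per the file headers. The same table holds FPKM values deposited by the authors, which equal the read count divided by the library's total and the gene's length for all 66024 values above 0, within a relative tolerance of 1e-06. The genome build was GRCm39, per the submitters' processing notes. The aligner, the counting tool, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands, and of near-identical copies, may not be separated. Coordinates are those of the deposited table, and the available reference of another build was not used here. Exon positions were not analysed here.

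Groups were taken from the genotype labels. Replicate numbers follow the order of the samples and pair nothing, and the labels do not say whether the libraries came from separate litters or batches, so p-values measure the spread between these samples, which may be technical. No pair of libraries agreed within counting noise: chi-square per gene was 8.23 to 12.1. Counts were scaled by TMM (factors 0.993 to 1.01) and filtered with filterByExpr (minimum count 10) in edgeR 4.0.16 under R 4.3.3, and CPM values use the TMM-scaled totals. The edgeR quasi-likelihood test, two-sided, was fitted to 3 groups with 1 residual degree of freedom for the comparisons with wild type and with Hez, and to 2 groups with 2 residual degrees of freedom for the comparison with both together. The common biological coefficient of variation was 0.114 and 0.105. Each gene's spread was moderated toward the trend over all genes, with 7.02 and 5.72 prior degrees of freedom. Standard errors and p-values thus draw largely on other genes. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05, and standard errors of log2 folds were taken as the fold divided by the square root of the F statistic. Hez against wild type was described without a test, from log2 CPM with a prior count of 2.

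In total 40 gene lists of pathways and cell types, with 558 members of which 551 are in the table, were fixed before the data were examined, as were the groups, the tests and most alternatives. Lists with at least 4 tested members (39, the Y-linked list being described only) were tested with camera from limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation, and with fry. For single libraries, a list's median was set against 10000 random lists of the same size, matched on mean expression. Named genes followed a fixed rule: Dnah9 always, and per comparison up to 10 per direction past the threshold, at 1 CPM or more, with both knockout libraries beyond both wild type and Hez, filled with the smallest p up to 5 per direction. Of each list the 2 to 4 members with the smallest p were named, and for Hez against wild type the 5 largest differences per direction at 5 CPM or more. Scgb3a1, Scgb3a2 and Bpifa1 also passed the threshold and are top members of the club cell list.

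The tests were tested on simulated counts with 200 changed genes per simulation and 5 simulations. For knockout against wild type, edgeR called 23.7%, 68.7% and 93.6% of genes changed 1.5-, 2- and 4-fold, and 0.0314% of unchanged genes. For knockout against both references it called 43.9%, 79.4% and 98.2%, and 0.0429% of unchanged genes. The simulations gave wild type and Hez the same mean, and gave every library the spread of the fitted trend over genes. That lone libraries vary like the knockout pair was thus built in, so these rates do not test it and may not hold for the real libraries. For the list test, the adipocyte markers and the inner dynein arm subunits were shifted by 0.5 on the log2 scale in each of 5 simulations. Of these 10 shifts, camera called 10 with the preset correlation, with 0 other lists called, and 0 with the estimated correlation. No other list was shifted. The simulated genes varied independently, so the 0 other calls do not measure errors where list members vary together. With the real counts, the preset correlation called lists in every other arrangement of a pair against a single library as well. The estimated correlation missed all shifted lists, so a lack of calls with it decides little. Alternatives were DESeq2 size factors, no filter and a stricter filter (mean of 10 CPM), the DESeq2 1.42.0 Wald test, limma-voom, a test against a fold of 1.5, limma on log2 FPKM with a pseudocount of 0.5, 0.1 or 1 (mean FPKM of at least 1) and after median centring, one reference group, and each library left out. The scaling shifted the median of all genes by -0.00122 with DESeq2 size factors and by -0.0122 with library totals only.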

Results

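RNA sequencing was performed on lung tissue of mice of the C57BL6 strain at 2 months of age, to find genes whose level differs when Dnah9, a heavy chain of the outer dynein arms that drive ciliary beating, is knocked out. The 4 libraries comprised 1 from a wild-type mouse, 2 labelled as Dnah9 knockout and 1 carrying the genotype label Hez, which the labels do not spell out and which is kept here as written. The total read count was 16106514 in the wild-type library, 16382227 and 15860478 in knockout libraries 1 and 2, and 16553480 in the Hez library. Between 16445 and 16571 genes had at least 1 read. The 10 most abundant genes took 6.80% to 7.37% of the reads, and mitochondrially encoded genes took 3.02% to 3.36%. Ddx3y, a Y-linked RNA helicase gene, stood at 128 to 139 CPM (the read count scaled to the library total) in all 4 libraries. The wild-type and Hez groups held 1 library each, so tests against either rest on the spread between the 2 knockout libraries, moderated over all genes. They assume that the lone libraries vary alike.

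Dnah9 (ENSMUSG00000056752, chromosome 11, 65722108 to 66059377 on GRCm39) had 917 reads in the wild-type library, 420 in the Hez library, and 240 and 254 in knockout libraries 1 and 2. This corresponded to 56.6 CPM in wild type (95% exact Poisson interval 53.0 to 60.4), 25.4 in Hez (23.0 to 28.0), 14.8 in knockout 1 (12.9 to 16.7) and 16.0 in knockout 2 (14.1 to 18.1). The intervals cover counting error only. Relative to wild type, Dnah9 stood at 44.9% in Hez and at 26.1% and 28.2% in the knockout libraries. Dnah9 fell by 1.88 on the log2 scale in the knockouts against wild type (SE 0.145, n = 2 against 1, edgeR adjusted p = 0.00864). Against Hez the difference was -0.73 (SE 0.152, edgeR adjusted p = 0.599), which did not pass. Counts per gene do not show which exons the remaining reads cover, and the deleted part of the gene is not given in the sources used here. The Dnah9 call against wild type was lost when log2 FPKM values were tested with limma (adjusted p = 0.669) and when wild type and Hez formed one group (adjusted p = 0.627). Of 169 tested genes within 5 Mb of Dnah9, 0 passed the threshold in edgeR, 9 had an unadjusted p below 0.05, and the median log2 fold was 0.01.

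**Figure D1:**
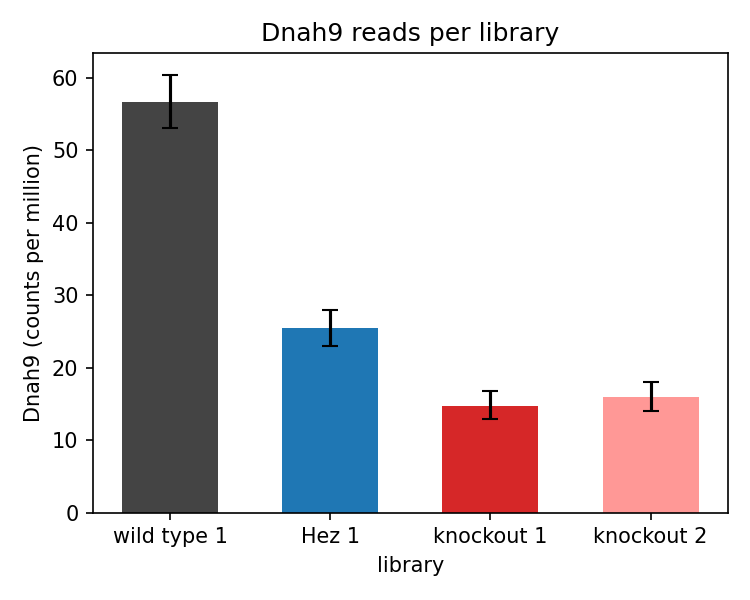
Dnah9 reads in each library, in CPM, with bars starting at 0 and error bars giving the 95% exact Poisson interval of the count. Wild type stands at 56.6, Hez at 25.4 and the knockout libraries at 14.8 and 16.0.

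The comparison of knockout with wild type is the one the series names, and it called 8 genes. Zbtb16, which encodes a zinc finger transcription factor induced by glucocorticoids, fell by 4.19 on the log2 scale (SE 0.124, edgeR adjusted p = 9.14e-06), from 190 CPM in wild type to 11.4 and 9.44 in the knockout libraries, while Hez stood at 129. Genes of airway secretory cells fell: Scgb3a1 and Scgb3a2, secretoglobins of the airway epithelium, by 1.06 (SE 0.089, adjusted p = 0.00864) and 0.88 (SE 0.0971, adjusted p = 0.0365), and Bpifa1, a secreted airway defence protein, by 1.33 (SE 0.129, adjusted p = 0.021). Cfd, the complement factor adipsin made by fat cells, fell by 1.09 (SE 0.126, adjusted p = 0.0482). Lrat, which esterifies retinol, rose by 1.25 (SE 0.105, adjusted p = 0.00864), and Zfp36, which destabilises cytokine messenger RNAs, rose by 0.91 (SE 0.0978, adjusted p = 0.0365). Hez also lay above wild type for both, at 84.4 against 47.95 CPM for Lrat and 231.5 against 148.3 for Zfp36. Against Hez the folds were 0.43 (edgeR adjusted p = 0.65) and 0.26 (adjusted p = 0.971), which did not pass.

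Zbtb16 (ENSMUSG00000066687) lies on chromosome 9 from 48565597 to 48747522, Cfd (ENSMUSG00000061780) on chromosome 10 from 79726687 to 79728489, and Lrat (ENSMUSG00000028003) on chromosome 3 from 82799886 to 82811280. Zfp36 (ENSMUSG00000044786) lies on chromosome 7 from 28076209 to 28079678, and Bpifa1 (ENSMUSG00000027483) on chromosome 2 from 153984800 to 153991139. Scgb3a2 (ENSMUSG00000038791) lies on chromosome 18 from 43897354 to 43900464, and Scgb3a1 (ENSMUSG00000064057) on chromosome 11 from 49554437 to 49555945. Scgb3a1, Scgb3a2 and Bpifa1 stood at 189, 318 and 260 CPM in Hez, against 522, 649 and 611 in wild type, so the knockout libraries did not lie beyond both reference libraries for them. Closest to the threshold without passing it, under the naming rule, were Junb (0.90, adjusted p = 0.208), Gja5 (0.59, adjusted p = 0.323) and Il33 (0.63, adjusted p = 0.323) on the higher side. On the lower side were Myl4 (-0.79, adjusted p = 0.0634) and Hspb7 (-1.03, adjusted p = 0.122). Of 15055 genes tested, 780 had an unadjusted p below 0.05, where 753 are expected by chance. The count of 8 was 16 with DESeq2, 4 with no filter or a stricter filter on low counts, 2 against a fold of 1.5 and 1 with limma on FPKM values.

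**Figure D2:**
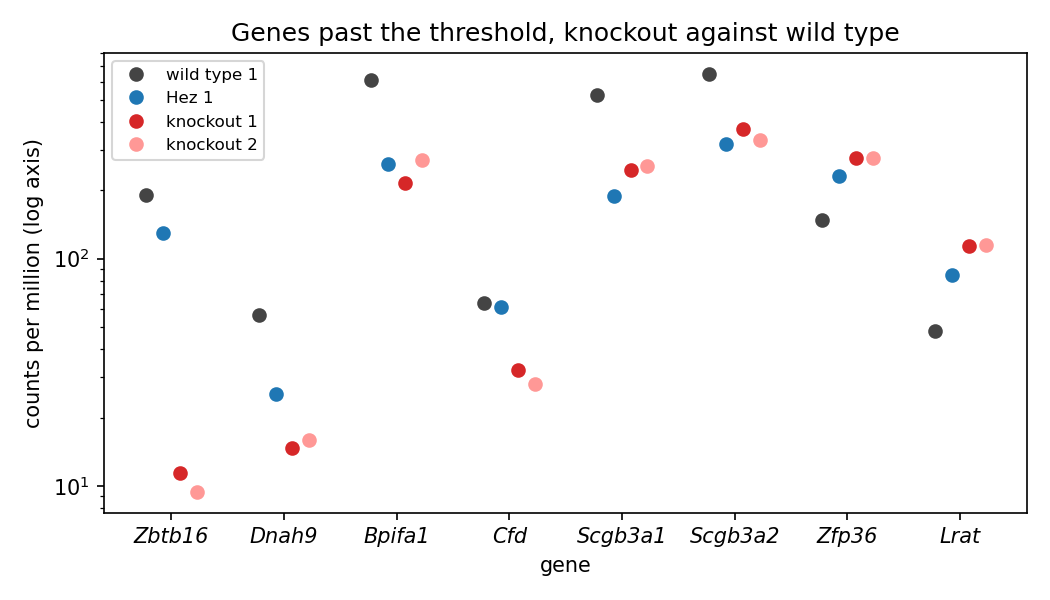
CPM on a log axis for the 8 genes that passed the threshold in the knockout against wild type, 1 point per library. Zbtb16 stands at 11.4 and 9.44 in the knockout libraries and at 190 and 129 in wild type and Hez, whereas Scgb3a1 stands at 189 in Hez and 245 and 255 in the knockouts.

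Genes of motile cilia lay lower in the knockout libraries than in wild type. The Hez library lay lower too, with medians against wild type of -0.56 for the spoke list, -0.64 for the multiciliated cell markers and -0.51 for the inner arms. All 25 tested genes of the radial spoke, central pair and nexin link list and all 24 tested multiciliated cell markers had negative log2 folds, with medians of -0.46 and -0.49, and 12 of 13 inner dynein arm subunits did so, with a median of -0.50. Past the threshold over all genes there were 0 members in each of these lists, and adjusted over the list alone 14, 9 and 9 members were lower. Examples were Dnah6 (-0.63, SE 0.101), Dnah3 (-0.59, SE 0.114) and Dnah10 (-0.50, SE 0.107) of the inner arms, Cfap44 (-0.50, SE 0.102), Cfap43 (-0.51, SE 0.108) and Hydin (-0.54, SE 0.116) of the axoneme, and the ciliated cell markers Cdhr3 (-0.60, SE 0.102) and Ccdc153 (-0.53, SE 0.101). The camera test with a preset correlation placed these lists below other genes, with adjusted p = 4.68e-19 for the spoke list, 3.29e-19 for the markers and 1.62e-13 for the inner arms, and adjusted p = 0.477 with an estimated correlation for each. The version with an estimated correlation missed all 10 simulated shifts of the adipocyte and inner arm lists, so it does not decide between a shift and none.

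The other cilia lists lay on the same side. The Hez library lay lower than wild type too, with medians of -0.36 for the outer arms and -0.58 for docking and assembly factors. Its medians were -0.19 for the transcription and centriole list and -0.10 for intraflagellar transport and BBSome genes. The outer dynein arm subunits without Dnah9 had a median of -0.32, with 8 of 11 lower (adjusted p = 0.000714), Dnah5 at -0.45 (SE 0.1) and Dynlrb2 at -0.52 (SE 0.145). Docking and assembly factors had a median of -0.41, with 15 of 16 lower (adjusted p = 7.1e-07), Efcab1 at -0.63 and Odad1 at -0.62. The list of multiciliated cell transcription and centriole amplification had a median of -0.34, with 11 of 14 lower (adjusted p = 0.000263), among them Foxj1, the main transcription factor of motile ciliogenesis (-0.55, SE 0.0974), and Gmnc (-0.85, SE 0.242). Intraflagellar transport and BBSome genes had a median of -0.08, with 19 of 24 lower (adjusted p = 0.0286), Ift57 at -0.66 and Ift88 at -0.43. Each of these 4 lists had adjusted p = 0.477 with an estimated correlation. The list of other axonemal or cytoplasmic dynein subunits was not distinguished from other genes (median -0.03, camera adjusted p = 0.797).

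Markers of other airway and muscle cells were lower as well. The Hez library again lay lower too, with medians against wild type of -0.68 for club cells, -0.64 for smooth muscle and -0.37 for skeletal muscle. Of 17 club and secretory cell markers 16 were lower, with a median of -0.42, 3 past the threshold over all genes and 14 adjusted over the list alone (camera adjusted p = 1.02e-29). Besides the 3 called genes, Muc5b, a gel-forming airway mucin, stood at -1.03 (SE 0.125, edgeR adjusted p = 0.0575). Smooth muscle and pericyte markers had a median of -0.41, with 10 of 11 lower and 7 adjusted over the list alone (camera adjusted p = 9.17e-12), Actg2 at -0.78 (SE 0.108) and the contractile regulator Cnn1 at -0.83 (SE 0.131). Skeletal muscle markers had a median of -0.32, with 8 of 9 lower (camera adjusted p = 0.00095), Tnnt3 at -1.50 (SE 0.257) and Mb, myoglobin, at -0.74 (SE 0.155). All 3 lists had adjusted p = 0.477 with an estimated correlation.

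Cardiac muscle genes, which mouse lung expresses in the walls of pulmonary veins, were lower in 13 of 14 members, with a median of -0.60 and 13 adjusted over the list alone (camera adjusted p = 7.22e-28). Myl4, an atrial myosin light chain, stood at -0.79 (SE 0.0982) and Tnnt2, cardiac troponin T, at -0.70 (SE 0.102). All 9 tested adipocyte markers were lower, with a median of -1.09, 1 past the threshold over all genes (Cfd) and 6 adjusted over the list alone (camera adjusted p = 1.48e-16). Car3 stood at -0.94 (SE 0.147) and Adipoq, the fat cell hormone adiponectin, at -1.18 (SE 0.246). Mesothelial markers had a median of -0.38, with 7 of 8 lower (camera adjusted p = 0.00316), Krt19 at -0.27 and Rspo1 at -0.59, and the list median was -0.13 in knockout 1 and -0.82 in knockout 2. With an estimated correlation, adjusted p = 0.477 for the cardiac and adipocyte lists and adjusted p = 0.495 for the mesothelial list.

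Clock output genes, which follow the day and night cycle, were lower in 10 of 11 members, with a median of -0.51 and 8 adjusted over the list alone (camera adjusted p = 4.04e-13). Tef stood at -0.56 (SE 0.101), Hlf at -0.95 (SE 0.208) and Per2 at -0.81 (SE 0.197). The 5 clock genes of the opposite phase had a median of 0.05 (camera adjusted p = 0.418). Against Hez their median was 0.10 (adjusted p = 0.0444, and adjusted p = 0.693 with an estimated correlation). The glucocorticoid-responsive list had a median of -0.21 and a mean of -0.60 (camera adjusted p = 9.6e-18), and of its 10 members Zbtb16 passed over all genes, with Fkbp5, a cochaperone of the glucocorticoid receptor, at -1.22 (SE 0.209) the other of 2 members lower adjusted over the list alone. The median of the glucocorticoid-responsive list against wild type was 0.19 in knockout 1 and -0.81 in knockout 2, so the libraries differed in sign. Both called lists had adjusted p = 0.477 with an estimated correlation.

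Alveolar type 2 cell markers were higher in 14 of 15 members, with a median of 0.26, 0 past the threshold over all genes and 9 adjusted over the list alone (camera adjusted p = 1.54e-07). Sftpc, a surfactant protein, stood at 0.18 (SE 0.0444), Chil1 at 0.35 (SE 0.0776) and Cxcl15 at 0.27 (SE 0.0638). Immediate early and heat shock genes, many of which respond within minutes to stimulation or tissue handling, were higher in 18 of 19 members, with a median of 0.52, 1 past the threshold over all genes (Zfp36) and 8 adjusted over the list alone (camera adjusted p = 4.69e-18). Junb stood at 0.90 (SE 0.145) and Nr4a1 at 1.76 (SE 0.379), and the list median was 0.29 in knockout 1, 0.80 in knockout 2 and 0.32 in Hez. MHC class II genes had a median of 0.26, with 8 of 9 higher (camera adjusted p = 0.00153), the invariant chain gene Cd74 at 0.27 and H2-Aa at 0.25. Alveolar macrophage markers had a median of 0.12, with 13 of 14 higher (camera adjusted p = 0.007), the chitinase-like gene Chil3 at 0.76 (SE 0.181) and Krt79 at 0.41. All 4 lists had adjusted p = 0.477 with an estimated correlation.

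Further lists passed the preset-correlation test. On the higher side, unfolded protein response genes had a median of 0.18 (camera adjusted p = 0.000263, and adjusted p = 0.526 with an estimated correlation), with the endoplasmic reticulum chaperones Hspa5 at 0.36 and Hsp90b1 at 0.35. Cholesterol and fatty acid synthesis genes had a median of 0.16 (adjusted p = 0.000633), with Hmgcs1 at 0.31 and Sqle at 0.29, and B cell markers a median of 0.36 (adjusted p = 0.00255), with Fcer2a at 0.60 and Cr2 at 0.53. Inflammatory cytokines and chemokines had a median of 0.25 (adjusted p = 0.00255), with the alarmin gene Il33 at 0.63 and Tnf at -1.07, and endothelial markers a median of 0.10 (adjusted p = 0.0186), with Cldn5 at 0.27 and Plvap at 0.21. These 4 lists had adjusted p = 0.477 with an estimated correlation. Monocyte and interstitial macrophage markers had a median of 0.18 (adjusted p = 0.00899), with Cd68 at 0.28 and Ccr2 at 0.30, and interferon-stimulated genes a median of 0.17 (adjusted p = 0.00908), with Ifi44 at 0.34 and Cxcl10 at 1.29, both with adjusted p = 0.493 with an estimated correlation. T and NK cell markers had a median of 0.23 (adjusted p = 0.007, and adjusted p = 0.699 with an estimated correlation), with Gzmb at 1.09 and Cd3g at 0.56. For these 5 immune lists the median against wild type was larger in knockout 1 than in knockout 2: 0.41 and -0.03 for inflammatory genes, 0.55 and 0.11 for B cells, 0.40 and 0.03 for T and NK cells, 0.32 and 0.07 for monocytes and macrophages, and 0.21 and 0.09 for interferon-stimulated genes. The values were 0.29 and 0.11 for the unfolded protein response, 0.15 and 0.12 for alveolar macrophage markers, and 0.18 and 0.27 for MHC class II genes.

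On the lower side, erythroid markers had a median of -0.20 (camera adjusted p = 0.0105), with the globin genes Hbb-bs at -0.20 and Hba-a1 at -0.15, whose near-identical copies can share reads. Cell cycle genes had a median of -0.28 (adjusted p = 0.027), with Cenpf at -1.18 and Bub1 at 0.65, and both lists had adjusted p = 0.477 with an estimated correlation. Mitochondrially encoded genes had a median of -0.13 (adjusted p = 0.0285, and adjusted p = 0.537 with an estimated correlation), with mt-Nd1 at -0.15 and mt-Nd6 at -0.20. Lists that did not pass were basal cells (adjusted p = 0.283), alveolar type 1 cells (0.12), neuroendocrine and tuft cells (0.68), neutrophils (0.0867), mast cells, basophils and eosinophils (0.797), and fibroblast and matrix genes (0.166), where Dcn stood at -0.41 and Lum at -0.70. In all, 31 of 39 lists were called with the preset correlation, 13 higher and 18 lower. Other arrangements of the libraries, a pair against a single one, called 11 to 26 lists with the same test. A call with the preset correlation therefore does not by itself show an effect of the genotype. With an estimated correlation 0 were called, with 0.0506 the smallest unadjusted p, and fry called 0, with 6 lists at an unadjusted p below 0.05. In the simulations the estimated correlation called 0 of 10 shifts, all of them of the adipocyte and inner arm lists. Its lack of calls therefore does not show that lists were unchanged.

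**Figure D3:**
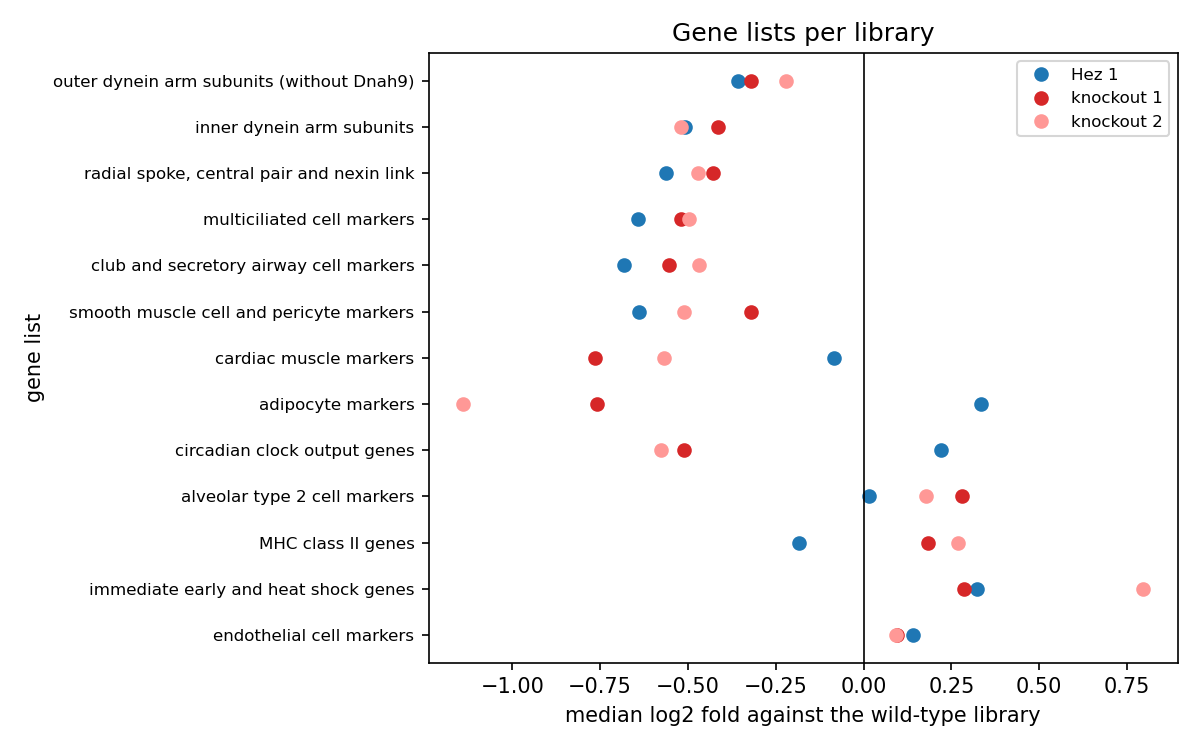
Median log2 fold of selected gene lists against the wild-type library, 1 point each for Hez, knockout 1 and knockout 2. Lists on which the knockout libraries differed, namely mucous and type 2, neutrophil, glucocorticoid-responsive and mesothelial, are not shown. For the multiciliated cell markers Hez stands at -0.64 and the knockouts at -0.52 and -0.50, whereas for adipocyte markers Hez stands at 0.34 and the knockouts at -0.76 and -1.14.

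Against the Hez library, Zbtb16 was the single gene called, having fallen by 3.63 on the log2 scale (SE 0.124, edgeR adjusted p = 2.85e-05). Several cilia lists were not distinguished from other genes in this comparison: the spoke list had a median of 0.10, with 18 of 25 higher (camera adjusted p = 0.145), the inner arm subunits a median of 0.02 (adjusted p = 0.927), and the list of multiciliated cell transcription and centriole amplification a median of -0.16, with 11 of 14 lower (adjusted p = 0.1). Nor were the outer arm subunits (median 0.135, 9 of 11 higher, camera adjusted p = 0.1) or the docking and assembly factors (median 0.138, 10 of 16 higher, adjusted p = 0.232). The multiciliated cell markers lay above other genes, with a median of 0.13 and 19 of 24 higher (adjusted p = 0.0175, and adjusted p = 0.693 with an estimated correlation). The smooth muscle list also lay higher (median 0.18, adjusted p = 0.00737, and adjusted p = 0.693 with an estimated correlation), with Actg2 at 0.40 and Cnn1 at 0.37. Scgb3a1 differed by 0.40 (edgeR adjusted p = 0.65) and Bpifa1 by -0.09 (adjusted p = 1).

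Lists that were lower than in wild type and also lower than in Hez were the adipocyte markers (median -1.32, 9 of 9 lower, camera adjusted p = 3.19e-29), the clock output genes (median -0.71, 10 of 11 lower, adjusted p = 8.92e-27), the cardiac muscle markers (median -0.59, 13 of 14 lower, adjusted p = 1.23e-20), the glucocorticoid-responsive genes (median -0.34, adjusted p = 1.23e-20) and the mesothelial markers (median -0.79, adjusted p = 1.74e-06). Each of these 5 lists had adjusted p = 0.693 with an estimated correlation. For the last pair the knockout libraries disagreed, with medians against wild type of 0.19 in knockout 1 and -0.81 in knockout 2 for the glucocorticoid-responsive genes, and of -0.13 and -0.82 for the mesothelial markers. Car3 stood at -1.32 (SE 0.145, edgeR adjusted p = 0.115), Tef at -0.78 (SE 0.1, adjusted p = 0.16) and Nr1d1, a clock repressor, at -0.86 (SE 0.116, adjusted p = 0.189). MHC class II genes were higher in 9 of 9 members (median 0.38, camera adjusted p = 2.85e-10), with Cd74 at 0.45, and alveolar type 2 markers in 14 of 15 (median 0.16, adjusted p = 2.27e-06), both with adjusted p = 0.693 with an estimated correlation. Spon2 (0.96, edgeR adjusted p = 0.115), Thbs1 (0.83, adjusted p = 0.299), Krt79 (1.02, adjusted p = 0.505) and Rnf144a (0.56, adjusted p = 0.522) led the genes on the higher side without passing. At an unadjusted p below 0.05 there were 694 genes, where 753 are expected by chance. Of the 39 lists 17 were called, and 0 with an estimated correlation, where the smallest adjusted p = 0.693.

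With wild type and Hez as one group, the one comparison with 2 libraries on each side, Zbtb16 fell by 3.94 (SE 0.201, edgeR adjusted p = 0.00109) and Cfd by 1.06 (SE 0.0975, adjusted p = 0.0446). Dnah9 stood at -1.42 (SE 0.326, adjusted p = 0.627). The next genes did not pass: Myl4 at -0.71 (adjusted p = 0.197), Car3 at -1.15 (adjusted p = 0.294) and Tef at -0.68 (adjusted p = 0.294) on the lower side. On the higher side stood Il33 at 0.57 (adjusted p = 0.358), Cyp26b1, which degrades retinoic acid, at 1.73 (adjusted p = 0.368), Neurl3 at 0.52 (adjusted p = 0.377), Rnf144a at 0.49 (adjusted p = 0.377) and Arl4c at 0.44 (adjusted p = 0.384). Both knockout libraries lay below both others in 12 of 14 cardiac muscle markers, 9 of 11 clock output genes and 7 of 9 adipocyte markers, where 2.33, 1.83 and 1.5 are expected by chance for genes that vary independently. They lay above both in 13 of 15 alveolar type 2 markers and 7 of 9 MHC class II genes, where 2.5 and 1.5 are. Members of a list can vary together, and only these of the 39 lists were counted in this way, so the counts do not exclude chance. Over 15055 genes, 2456 lay below and 2636 above both others. This was 33.8% in both directions together, where 33.3% is expected by chance. Of 14674 genes 2 were called, 741 had an unadjusted p below 0.05 and 734 are expected by chance. The count was 33 with DESeq2, 107 without knockout replicate 1, 24 without knockout replicate 2, 8 without Hez and 1 without wild type. Of 39 lists 23 were called, and with an estimated correlation 0 were, where the smallest adjusted p = 0.177.

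Hez and wild type were each represented by 1 library, so their difference has no replicate check. Of genes with a mean of at least 5 CPM, 50 differed by more than 2-fold, 7 higher and 43 lower in Hez, and the 2 knockout libraries differed from each other by as much in 98 genes. Knockout 2 also differed by that much from wild type in 99 genes and from Hez in 90. Knockout 1 differed from wild type in 50 and from Hez in 30. Immediate early genes led the higher side, with Fosb at a log2 fold of 1.75, Egr1 at 1.46 and Fos at 1.34, together with the cytokine gene Il1b at 1.36 and the receptor kinase gene Ros1 at 1.12. On the lower side stood Clca1, a goblet cell product, at -2.52, Calml3 at -2.31, Serpina9 at -2.23 and Tmc5 at -1.94, and Chil4, which had 29 reads in wild type and 0 in Hez and reached the mean of 5 CPM only through knockout 2, at 54.0 CPM. The medians of the spoke list (-0.56), the multiciliated cell markers (-0.64), the club cell markers (-0.68) and the smooth muscle list (-0.64) were each lower than those of all 10000 random lists of matched size and expression. Random lists hold genes drawn independently, whereas list members can vary together. Between the knockout libraries (2 less 1), lists also lay beyond all random lists. These were the mucous and type 2 list (1.94), neutrophil markers (-1.64), glucocorticoid-responsive genes (-0.68), mesothelial markers (-0.58) and immediate early genes (0.54). There the smooth muscle list (-0.13) lay below the 95% random range, and the spoke, multiciliated and club cell lists lay within it. The adipocyte list had a median of 0.34 (percentile 99.9) and the clock output list of 0.22 (percentile 99.9).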

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

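The fit of the lists without Hez and Dnah9 relative to ciliated genes were chosen after seeing the data. The list test against Hez was planned, but its use as an alternative here was chosen afterwards. No paired analysis was possible because the labels give no replicate numbers. For knockout against wild type, the count of 8 genes became 4 with no filter, 4 with the stricter filter, 16 with DESeq2, 2 against a fold of 1.5, 1 with limma on log2 FPKM at each pseudocount (0.5, 0.1 and 1) and 1 after median centring, and 2 with wild type and Hez as one group. It was 9 with DESeq2 size factors, 9 with voom and 8 without Hez, of which 7 were among the 8. For knockout against Hez, the count of 1 became 7 with DESeq2, and 0 with limma on log2 FPKM at pseudocounts of 0.5 (558 genes at an unadjusted p below 0.05) and 0.1 (560) and after median centring (550). For knockout against both, the count of 2 became 1 with the stricter filter, 33 with DESeq2, 1 with voom, 1 against a fold of 1.5, 1 with limma on FPKM at pseudocounts of 0.5 and 0.1 and after centring, and 0 at a pseudocount of 1 (648 at an unadjusted p below 0.05). With 1 library left out it ranged from 1 (without wild type) to 107 (without knockout replicate 1), with 8 without Hez and 24 without knockout replicate 2. With 1 knockout library left out, the other 2 comparisons have no residual degrees of freedom and give folds only. Dnah9 against wild type lost its call with limma on FPKM, at -1.48 (pseudocount 0.5), -1.79 (0.1), -1.22 (1) and -1.46 (centred), with adjusted p from 0.624 to 0.733, and with one reference group, at -1.42 (adjusted p = 0.627). Its adjusted p otherwise ran up to 0.0487, and the folds without knockout replicate 1 and without replicate 2 were -1.82 and -1.93. Of 39 lists 31 were called, 0 with an estimated correlation, 0 with fry, 17 against Hez and 31 without Hez. Hez against wild type had 219 genes beyond 2-fold at 1 CPM and 25 at 10 CPM, in place of 50. The cause of these differences was not tested. Across 97 named gene results, 1329 alternatives left 1239 in the same direction and, where a test was possible, on the same side of the threshold, with 57 weaker, 30 stronger and 3 of the opposite sign, these being folds with no test. Only results past the threshold could become weaker, and most of the 97 were not past it. The 1239 therefore does not measure how stable the calls were. Without knockout replicate 2, Retnla was at -0.0107 (2.85 without knockout replicate 1) and Chil4 at -2.96 (4.82 without replicate 1), and without replicate 1 Csf3r was at -0.40 (0.94 without replicate 2). The alternative without sex-chromosome genes was not run, since Y-linked genes stood at like levels in all libraries.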

Other observations

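The 2 knockout libraries differed from each other in genes of mucous secretion and type 2 immunity. Clca1, secreted by goblet cells, had 9379 reads in knockout 2 and 121 in knockout 1, with 923 in wild type and 162 in Hez. Retnla, induced by type 2 cytokines, stood at 888 CPM in knockout 2, 122 in knockout 1, 123 in wild type and 54.2 in Hez, and the anion exchanger gene Slc26a4 at 73.8, 16.0, 8.64 and 5.20. Chil4 had 859 reads in knockout 2 and 2 in knockout 1, and reads shared with its close relative Chil3 cannot be excluded. The mucous and type 2 list passed the preset-correlation camera test against wild type (median 1.04, adjusted p = 0.0256, and adjusted p = 0.722 with an estimated correlation), with medians of 1.37 in knockout 2 and -0.62 in knockout 1 against wild type. Neutrophil markers differed the other way, with medians of 0.51 in knockout 1 and -1.14 in knockout 2, and Csf3r stood at 130 CPM in knockout 1 and 51.4 in knockout 2.

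The tests of the 3 patterns that follow were chosen after the patterns were seen, including the further fat and heart genes, and only the counts over other arrangements of the libraries were planned. The first pattern is the lower level of airway genes in the knockout libraries than in wild type. Less conducting airway in the knockout and Hez samples may account for it, as may more airway in the single wild-type sample: the club cell and smooth muscle lists lay below the range of random lists in 6 of 6 comparisons of a library with wild type, but all 6 share that wild-type library, so the count decides nothing. An effect shared by both genotypes cannot be told apart from this, with a ciliated median in Hez of -0.551 (95% bootstrap interval over genes -0.603 to -0.494). An effect of the knockout that Hez does not share cannot be told apart either: the ciliated median between knockout and Hez was 0.102 (0.0512 to 0.147, 64 of 89 genes higher), but there is 1 Hez library, the interval holds no spread between samples, and less airway in that sample would hide such an effect. Less airway as the whole cause of the Dnah9 difference between knockout and wild type is argued against. Dnah9 lay -1.42 from the ciliated median there, and 0 of 89 ciliated genes were as low in either knockout library. In Hez 0 were as low too, but the margin was small. Dnah9 lay -0.601 from the ciliated median of Hez, at -1.151 against -1.1 for the lowest ciliated gene, so the Hez library does not decide this.

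The second pattern is the lower level of Zbtb16, Fkbp5 and clock output genes in both knockout libraries. Lower glucocorticoid exposure cannot be told apart from other causes in either, since each value comes from 1 library and its interval is over genes. The 8 other responsive genes had a median log2 difference from the mean of wild type and Hez of 0.19 (0.0394 to 0.377) in knockout 1, where Fkbp5 was at -0.87, and of -0.618 (-1.4 to 0.0658) in knockout 2. Collection at another time of day could lower clock output genes, and it cannot be told apart from a genotype effect: clock genes of the opposite phase had a median of 0.0878 (range -0.12 to 0.465), against Hez 4 of 5 were higher (camera adjusted p = 0.0444, and adjusted p = 0.693 with an estimated correlation), and collection times are not given in the sources used here. An effect of the genotype stays open and was not tested separately.

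The third pattern is the lower level of adipocyte and cardiac muscle genes in both knockout libraries. Less of the tissue next to the lung, or of pulmonary vein muscle, in the knockout samples may account for the cardiac part: of 22 further cardiac genes outside the fixed list, 18 had both knockout libraries below both others, where 3.67 are expected by chance for genes that vary independently. For fat the test was open, with 8 of 16 further adipocyte genes doing so and 2.67 expected by chance. A change in gene expression within these cells would give lower values as well and was not tested, so the genotype stays among the open explanations.

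Other arrangements of the libraries were too few for a share under 0.05. For knockout against both references the real arrangement called 2 genes and the highest of the others 0, with 1 of 3 arrangements as high. For a pair against a single library, the real arrangement of knockout against wild type called 8 genes and the highest other 99, with 4 of 12 as high. That highest one set wild type and Hez against knockout 2 alone. Such a count depends on how alike the paired libraries are, so by itself it does not show that knockout 2 stands apart. Of genes with a mean of at least 5 CPM, knockout 2 differed by more than 2-fold from each other library in 90 to 99. The pairs without knockout 2 differed in 30 to 50. For lists the real arrangement called 31 and the highest other 26, with 1 of 12 as high, and every other arrangement called at least 11 lists with the preset correlation.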
